A study of Mus musculus with 8 samples.

How the data were processed

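RNA was sequenced from mouse decidua, the maternal tissue that forms around the implanting embryo, at embryonic day 6.5. Per the labels, the myometrium and the embryo were cleared away under a dissecting microscope, total RNA was column-purified, and libraries followed standard Illumina protocols. There were 4 samples with the floxed Tgfbr1 gene (also called Alk5) and no Cre, called control, and 4 samples that also carried Pgr-Cre, called knockout. Replicate numbers 1 to 4 (control) and 5 to 8 (knockout) come from the sample titles. The titles hold a further number per sample whose meaning is not stated, and nothing in the labels says that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

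The deposited count table holds raw read counts per gene symbol for 54392 genes, as whole numbers with unequal totals. Per the submitters' processing notes, the genome build was GRCm38 and edgeR was used. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies such as the T cell receptor constant regions, granzymes, killer lectin receptors and globins, may be split between symbols. Of 13 symbols of genes encoded in mitochondria that were looked for, 0 were in the count table, so these genes were not tested. The authors' deposited table of their own comparison gives log2 fold changes and mean log2 CPM for 12099 genes. Its p-value and FDR columns are the authors' own, per the file headers, and the edgeR test behind them is not stated. Its 2 columns of group means are, from their values, a signal the authors made by scaling counts between samples and averaging them. Every count column was matched to a sample by its number, and 0 columns were left unmatched.

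Tests used the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10), which left 17928, and scaled with TMM factors. The quasi-likelihood F-test (glmQLFit with robust = TRUE, glmQLFTest) compared knockout with control with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Positive log2 changes mean higher in the libraries labelled knockout. The standard error given with a log2 change is its size divided by the square root of the F statistic, an approximation. Values per library are TMM-scaled CPM. Total counts per sample ranged from 45573335 to 62493874. Principal components used log2 CPM with a prior count of 2 over the 2000 most variable genes.

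The samples, tests, gene lists and alternatives were fixed before the data were examined, apart from those said to be chosen later. The later ones include the tests of blood content and of myometrium and a list of imprinted genes. The 38 lists cover pathways and markers of cell types that decidua or its dissection could hold, and Tgfbr1 was left out of each. Lists with at least 3 tested genes, 35 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with adjustment over lists, and again with an estimated correlation and with fry. The Y-linked list, the embryonic globins and the list of genes encoded in mitochondria had 0 tested genes. Named genes are Tgfbr1 and Pgr, the 12 largest changes in each direction among called genes with a mean log2 CPM of at least 1 and no overlap between groups (names of predicted genes, RIKEN clones and bare clone accessions left out), and up to 4 members of each list with the smallest p. Genes outside this rule are said to be chosen after their values were seen. Coordinates are those of GENCODE M21 on GRCm38, in which 98.8% of the symbols were found.

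The test was run on simulated data for this comparison (17928 genes, 200 of them changed, 4 samples against 4). It called 69% of the genes changed 2-fold and 92% of those changed 4-fold, 3.59% of its 167 calls were unchanged genes, and it made 0 calls when no gene was changed. The simulated genes varied independently of each other, so these rates do not cover structure shared by many genes in the real libraries.

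Alternatives were median-of-ratios, total count and upper quartile scaling, no filter on low counts, a filter of 1 CPM in 4 samples, the edgeR likelihood ratio test, limma-voom with and without sample quality weights, DESeq2 1.42.0 (with its own size factors and filter), 1 surrogate variable from sva 3.50.0, an adjusted p threshold of 0.01, and each library left out in turn. Leaving out control 1 and knockout 7 together, and list tests with the surrogate variable, were added after the data were seen. Single values were compared with two-sided exact permutation tests, whose smallest p for 4 against 4 is 0.0286. Figures were drawn with matplotlib 3.10.9.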

Results

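Gene expression was measured by RNA sequencing in decidua at embryonic day 6.5 from 4 control samples and 4 samples labelled as Tgfbr1 knockouts made with Pgr-Cre, which acts in cells that express the progesterone receptor. The comparison asks which decidual transcripts differ when the type I receptor for TGF-beta is targeted. The control samples had no Cre, so an effect of carrying Pgr-Cre cannot be told apart from one of targeting Tgfbr1. Total counts ranged from 45573335 to 62493874 per sample. They averaged 50158499 ± 4179366 (SD, n = 4) in control and 57743055 ± 4186421 (SD, n = 4) in knockout (exact permutation p = 0.0857).

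Tgfbr1 (chromosome 4, 47353222 to 47414931) was higher, not lower, in the libraries labelled knockout. Its level, in counts scaled to library size (CPM), was 73.0, 79.9, 71.2 and 73.0 in control 1 to 4 and 90.7, 119.7, 102.7 and 105.2 in knockout 5 to 8. The log2 change was 0.49 ± 0.085 (SE, edgeR quasi-likelihood test, adjusted p = 0.0186). The call was lost without control 1 (adjusted p = 0.056) or control 3 (adjusted p = 0.0584). The counts cover the whole gene and a floxed allele loses only part of it, so they do not check the deletion. Every direction given here therefore rests on the labels alone, and knockout stands for libraries labelled knockout. Pgr (chromosome 9, 8899833 to 8968611), the locus that drives Cre, was at 385 ± 20.8 CPM (SD, n = 4) in control and 355 ± 30.7 CPM (SD, n = 4) in knockout, with an adjusted p of 0.452.

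**Figure D1:**
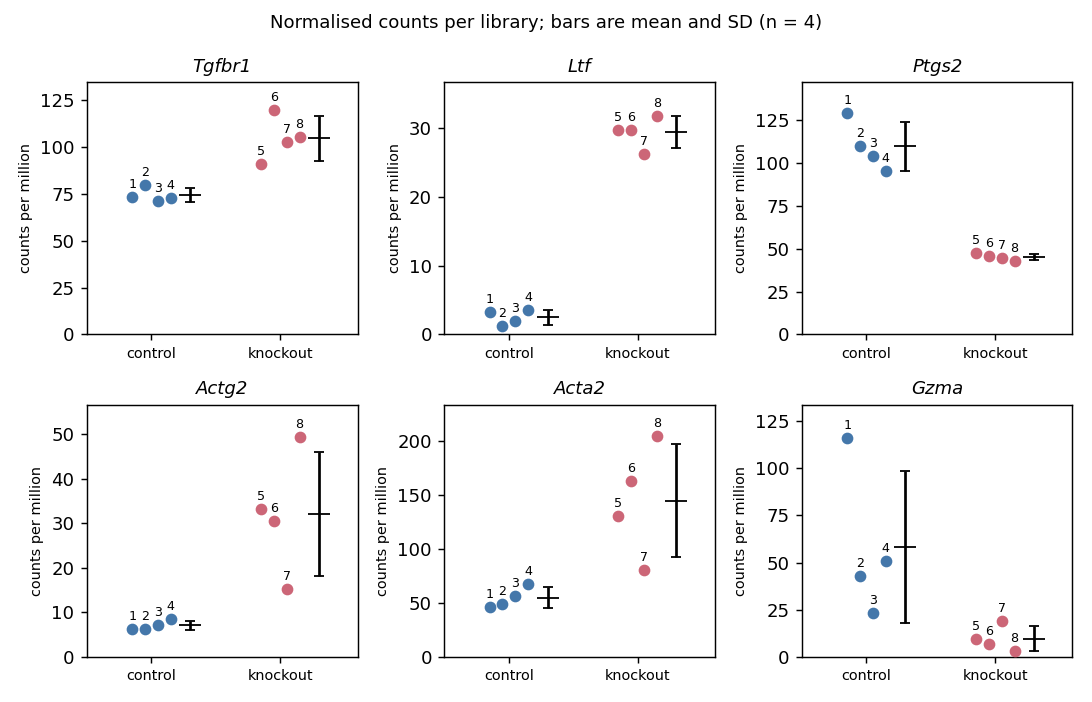
Normalised counts in CPM (vertical axis, starting at 0) of 6 genes in each library, numbered by replicate, with the mean and SD of each group (n = 4). Tgfbr1 lies between 71.2 and 79.9 CPM in control and between 90.7 and 119.7 CPM in knockout, and Gzma reaches 115.9 CPM in control 1.

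Of 17928 genes tested, 674 changed, 382 of them higher and 292 lower in knockout, and 300 changed at least 2-fold (172 higher, 128 lower). The groups did not overlap for 11.9% of all tested genes, against 2.86% expected by chance. The share was 99.6% among the changed genes, which the call itself largely fixes, so it is not further evidence. The number of calls moved by over 1.5 times whichever library was left out: it was 261, 378, 274 and 438 without control 1 to 4, and 271, 226, 1235 and 291 without knockout 5 to 8. Of 67 called genes named by the rule besides Tgfbr1, 22 kept their call whichever library was left out, among them Ltf, Ptgs2, Vipr1, Actg2, Igf1, Il7 and C2.

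**Figure D2:**
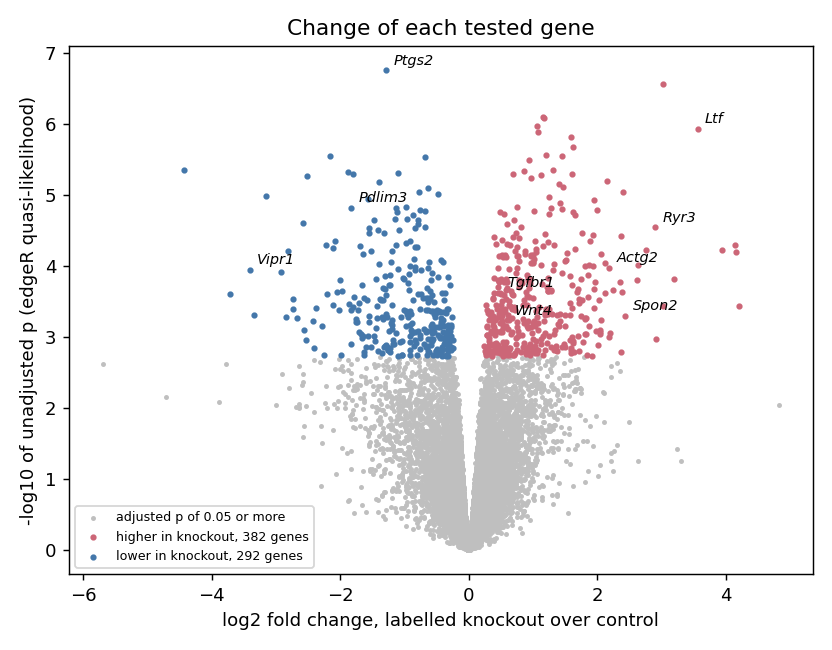
Log2 fold change of knockout over control (horizontal) against the −log10 of the unadjusted p of the edgeR quasi-likelihood test (vertical) for 17928 genes. The 382 genes called higher and the 292 called lower are coloured, and Ltf lies far to the right with a log2 change of 3.56.

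The first principal component held 47.8% of the variance and separated the groups (exact permutation p = 0.0286, the smallest that 4 against 4 can give). Control libraries lay between −45.9 and −8.6 on it, and knockout 7, at −0.72, lay nearest to them. The other knockout libraries lay between 20.3 and 40.6.

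**Figure D3:**
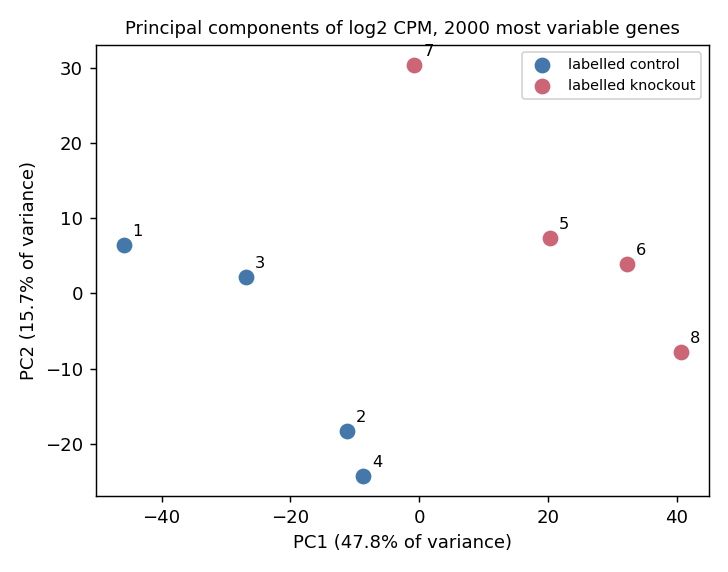
First and second principal components of log2 CPM of the 2000 most variable genes, in arbitrary units, with 1 point per library numbered by replicate. Control libraries lie to the left of every knockout library, and knockout 7 lies closest to control.

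Of the 674 called genes, 487 pass the rule for naming (mean log2 CPM of at least 1, no overlap between groups, no predicted genes or clones), and some of the others, at lower expression, had larger changes in either direction. The largest increase among the 487 was that of Ltf, which encodes lactoferrin, an oestrogen-responsive secretory protein of uterine epithelium. Ltf (chromosome 9, 111019271 to 111042767) rose from 2.48 ± 1.06 to 29.3 ± 2.31 CPM (SD, n = 4 each), a log2 change of 3.56 ± 0.298 (SE, adjusted p = 0.00333). Ryr3, an intracellular calcium channel, rose by 2.90 on the log2 scale and Slc18a3, the vesicular acetylcholine transporter, by 2.64. Spon2, a secreted matrix protein, rose by 2.44 and Actg2, smooth muscle gamma actin, by 2.19. The other increases named by the rule were Cd200r4 (2.92), Doxl2 (2.12), Brinp2 (2.06), Bex1 (2.05), Dsp (1.99), Clstn2 (1.95) and Osr1 (1.93). Among the decreases, Vipr1, a receptor for vasoactive intestinal peptide (chromosome 9, 121642716 to 121672954), had a log2 change of −3.41 ± 0.501 (SE, adjusted p = 0.0131). Capn6 had −2.38, Ccdc141 −2.12, Pdlim3 −1.83, and Elovl2, a fatty acid elongase, −1.74. The other decreases were Necab2 (−2.57), Serpinb6c (−2.28), Serpina3g (−2.02), Lrrtm1 (−1.81), Ear2 (−1.72), Trpc4 (−1.71) and Trbc1 (−1.66). Serpina3g, Serpinb6c, Ear2, Cd200r4 and Trbc1 belong to families of similar copies, and their counts are uncertain to that extent.

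Genes of decidualisation and hormone response moved both ways. Ptgs2, the inducible cyclooxygenase (chromosome 1, 150100031 to 150108227), fell from 109 ± 14.4 to 45.1 ± 1.83 CPM (SD, n = 4 each) and had the lowest adjusted p, 0.00244. Igf1 fell (log2 change −1.14), as did Il11ra1 (−0.45), Ccnd3 (−0.42) and Fst (−0.51), whereas Wnt4 rose (0.60). Cyp11a1, the side chain cleavage enzyme of steroid synthesis, rose (0.75), as did the prostaglandin receptor Ptger4 (1.19). Acod1 rose from a low level (2.04). Of these genes, Ptgs2, Igf1 and Cyp11a1 kept their calls whichever library was left out. Il11ra1, Ccnd3, Fst, Wnt4, Ptger4 and Acod1 did not. Their highest adjusted p in the edgeR quasi-likelihood test was, in that order, 0.0782, 0.102, 0.126, 0.0794, 0.0806 and 0.1. Of 37 decidualisation genes, 2 were higher and 3 lower over all genes, and 7 were higher and 3 lower adjusted over the list alone. The median log2 change of that list was −0.03 (camera adjusted p = 0.957). The progesterone and oestrogen response list had a median of 0.14 (2 of 23 higher, 2 lower, or 6 and 2 adjusted over the list alone, camera adjusted p = 0.596). The steroid and prostaglandin list had −0.11 (2 of 19 higher, 1 lower, or 2 and 3 adjusted over the list alone, adjusted p = 0.297).

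Camera with the preset correlation called 11 of the 35 lists. With an estimated correlation it called 0, and fry called 6 (matrix proteases, which camera did not call, and basement membrane, cholesterol synthesis, WNT signalling, complement, and epithelium and glands). The cholesterol synthesis list was lower: 5 of 22 genes fell over all genes and 15 adjusted over the list alone, with a median of −0.41 (adjusted p = 8.39e-09, and adjusted p = 0.358 with an estimated correlation). Its examples were Idi1 (−0.83), Cyp51 (−0.53), Msmo1 (−0.43) and Dhcr24 (−0.88). The endoplasmic reticulum stress list had a median of −0.25 (adjusted p = 4.22e-06, and adjusted p = 0.445 with an estimated correlation), yet 0 of its 22 genes were called, over all genes or adjusted over the list alone. The chaperone Hspa5 had −0.33 with an adjusted p of 0.0787.

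Basement membrane genes were higher as a list (median 0.31, adjusted p = 0.0012, and adjusted p = 0.358 with an estimated correlation). Lamb2, a laminin chain, rose by 0.73 and Col18a1 by 0.39. Neither kept its call whichever library was left out (highest adjusted p of the edgeR quasi-likelihood test 0.0674 and 0.0937). In all 2 of 18 rose over all genes, and 8 rose and 2 fell adjusted over the list alone. WNT signalling had a median of 0.28 (adjusted p = 0.00531, and adjusted p = 0.358 with an estimated correlation). There 2 of 28 genes rose, or 7 with 2 lower adjusted over the list alone. The 2 were Wnt4 and Sfrp5, and Sfrp5 (0.79) is known as a secreted antagonist of WNT ligands. Complement had a median of 0.12 (adjusted p = 0.0439, and adjusted p = 0.373 with an estimated correlation). Its 4 higher genes of 18 (5 adjusted over the list alone) were C2 (1.20), C1ra (0.58), C1s1 (0.67) and Cd59a (0.63), an inhibitor of the complement membrane attack. The complement call was lost without control 2 (adjusted p = 0.0881), control 4 (0.0761), knockout 5 (0.064) or knockout 8 (0.0648). Its median was 0.029 without control 1, 0.030 without knockout 8, 0.204 without knockout 7, 0.188 with no filter on low counts and 0.060 with 1 surrogate variable. With that variable the medians of WNT signalling and endoplasmic reticulum stress were 0.16 and −0.16.

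Markers of uterine natural killer cells, the main lymphocytes of early decidua, were lower as a list. The median log2 change was −1.28, and 30 of 31 tested members had values below 0 (adjusted p = 5.82e-12, and adjusted p = 0.445 with an estimated correlation). Only Il18r1 (−1.07) and Cd244a (−1.63) were called over all genes, against 19 adjusted over the list alone. Neither kept its call whichever library was left out (highest adjusted p of the edgeR quasi-likelihood test 0.103 and 0.127). Gzma had −2.59 with an adjusted p of 0.0666, and Gzmf −2.65 with 0.0584. Gzma was at 115.9, 42.7, 23.3 and 51.1 CPM in control 1 to 4 and at 9.48, 6.95, 19.2 and 3.15 CPM in knockout 5 to 8. The cytokine list that supports these cells had a median of −0.38 (adjusted p = 0.00531, and adjusted p = 0.445 with an estimated correlation). In it Il7 fell (−1.57) and so did Il15ra (−0.94), the receptor chain that presents interleukin 15, which makes 2 of 11, or 6 adjusted over the list alone. Il7 kept its call whichever library was left out, but Il15ra did not (highest adjusted p of the edgeR quasi-likelihood test 0.0568). The call of the cytokine list was lost without knockout 8 (adjusted p = 0.115) and with 1 surrogate variable (adjusted p = 0.0612). Its median was −0.22 without knockout 6 or knockout 8.

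**Figure D4:**
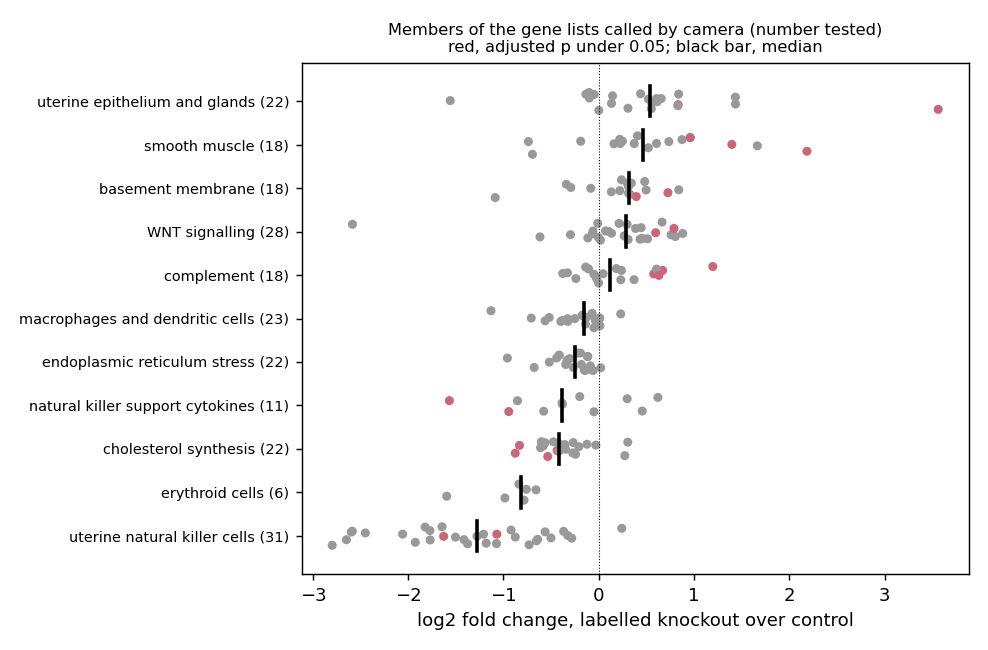
Log2 fold change of each tested member (points, red where the adjusted p was under 0.05) of the 11 lists called by camera with the preset correlation, with the median of each list as a bar and the number tested in brackets. The uterine natural killer list has a median of −1.28 with 2 members called, and the erythroid list lies wholly below 0.

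Red cell genes had a median of −0.81 with 0 of 6 called over all genes and 6 lower adjusted over the list alone (camera adjusted p = 0.00135, and adjusted p = 0.445 with an estimated correlation). Their median was −0.46 without control 1 and −0.43 with 1 surrogate variable. Macrophage and dendritic cell markers had a median of −0.15 with 0 of 23 called (adjusted p = 0.029, and adjusted p = 0.721 with an estimated correlation). That call was lost without control 1 (adjusted p = 0.071), control 3 (0.058), knockout 6 (0.285) or knockout 8 (0.0648), and the median was 0.0038 with 1 surrogate variable, −0.08 without knockout 6, −0.30 without control 2 and −0.26 without knockout 7. Smooth muscle markers had a median of 0.46 (adjusted p = 0.000767, and adjusted p = 0.445 with an estimated correlation). In that list 3 of 18 rose, or 8 with 2 lower adjusted over the list alone. The 3 were Actg2 (2.19), Acta2 (1.40) and Tpm2 (0.96), while Myh11, smooth muscle myosin, chosen after its values were seen, had 0.22 with an adjusted p of 0.447. Acta2 and Tpm2 lost their calls without any one of control 1 to 3 or knockout 5, 6 or 8, and with no filter on low counts. The smooth muscle median was 0.28 with 1 surrogate variable. Epithelial and glandular markers had a median of 0.54 (adjusted p = 0.00084, and adjusted p = 0.373 with an estimated correlation). There Ltf and Epcam (0.83) rose, 2 of 22, or 7 adjusted over the list alone.

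The lists below were not called by camera with all samples at the scaling and filter chosen beforehand. TGF-beta receptors and SMADs had a median of 0.07 (1 of 19 higher, also adjusted over the list alone), where Acvr2a rose (0.40) and Tgfbr2 had −0.39 with an adjusted p of 0.186. Ligands and antagonists had a median of −0.08 and a mean of 0.04, with Bmp7 (0.93) and Inhba (0.92) higher and Fst lower, and 4 higher and 1 lower adjusted over the list alone. Genes known to be induced by TGF-beta had a median of −0.05 and a mean of 0.06, with Acta2 and Cdkn2b (0.69) higher and 6 in each direction adjusted over the list alone. Fibrillar collagens and matrix had a median of 0.06 and a mean of −0.04, with Fmod (−1.33) and Col6a3 (−1.19) lower, and 3 higher and 6 lower adjusted over the list alone. Matrix proteases and inhibitors had 0.19, with Plat (0.55), Plaur (0.70) and Mmp23 (0.42) higher, the same number of 3 adjusted over the list alone, and a camera adjusted p of 0.0546. Lymphatic endothelium had −0.56, with Lyve1 (−1.60) and Mmrn1 (−1.65) lower, also 2 adjusted over the list alone. T cells had −0.39, with Trbc1 lower and Cd8a (1.84, both group means below 1 CPM) higher, and 1 higher and 4 lower adjusted over the list alone. The medians were −0.15 for hypoxia and glycolysis (Slc2a1 higher, 0.56), −0.07 for cell cycle, −0.03 for p53 and apoptosis, −0.07 for interferon response, −0.25 for immediate early genes and −0.04 for coagulation (Plat higher). They were 0.12 for B cells, −0.13 for neutrophils and mast cells, 0.48 for trophoblast and −0.03 for endoderm and epiblast. Some were called with 1 library left out, another scaling or filter, or 1 surrogate variable, always at the preset correlation, and an estimated correlation was not run in those settings. With all samples the estimated correlation gave an adjusted p of 0.986 for cell cycle and for interferon response, 0.849 for immediate early genes, 0.721 for T cells and for hypoxia and glycolysis, 0.445 for lymphatic endothelium and 0.373 for matrix proteases. The cell cycle list was called without control 1 (median −0.14, adjusted p = 8.16e-05) and with 1 surrogate variable (−0.14, adjusted p = 0.00024), and its median was −0.01 without control 2. Interferon response was called without control 4 (−0.18, adjusted p = 0.043) or knockout 7 (−0.22, adjusted p = 0.0374). Immediate early genes were called without control 2 (−0.34, adjusted p = 0.00363) or knockout 5 (−0.34, adjusted p = 0.00581), T cells without control 2 (adjusted p = 0.0227) or knockout 5 (0.0292), hypoxia and glycolysis without knockout 5 (0.00323), and lymphatic endothelium without control 4 (0.042). With all samples, T cells were called with total count scaling (0.0385) and with the filter of 1 CPM (0.0125), immediate early genes with total count scaling (0.04) and with no filter (0.0324), and lymphatic endothelium with no filter (0.0459). Matrix proteases were called without control 1 (0.0272), control 3 (0.0328) or knockout 7 (0.0374). Angiogenic factors (−0.0065, Edn1 and Fgf2 higher), inflammatory cytokines (−0.0037, Cxcl14 higher), blood endothelium (−0.0033) and pericytes (−0.0080) changed sign under total count and upper quartile scaling. In TGF-beta ligands, TGF-beta induced genes, fibrillar collagens, angiogenic factors, coagulation, B cells, blood endothelium and pericytes, the median, the mean and the camera direction did not all have the same sign.

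The authors' deposited table, made from the same samples, held 12099 genes, of which 948 had an FDR under 0.05 (496 higher and 452 lower). Among 12098 genes in both, 443 calls were shared, all with the same sign, of 506 calls made here, and 39.7 would be shared by independent lists. Log2 changes ranked almost identically across genes (Spearman rho 0.999997), with a median offset of 0.0099, which is not independent evidence because the counts are the same. Tgfbr1 was also higher in the authors' deposited table, by 0.50 with an FDR of 0.000799.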

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

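The tests of blood content and of myometrium were chosen only after the results they bear on were seen, as was the demand that the natural killer values clear their bound by more than the spread between libraries. The myometrium test was also changed after its value was seen. Its first form had no lower limit on expression and took the standard error over genes as spread, and it argued against myometrium. Myh11, Tagln, Myl9 and Myocd were named after their values were seen.

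In 124 groups of 4 samples, 7 held a sample far from its group by Dixon's ratio, and chance alone gives about 6.2. In knockout 5, Brinp2 was at 2.37 log2 CPM against 3.26 to 3.34 in the other knockout libraries. In knockout 7, Dsp was at 2.45 log2 CPM against 3.98 to 4.27. In knockout 8, Necab2 was at −0.14 (others 0.43 to 0.52) and Lrrtm1 at 2.42 (others 2.77 to 2.83). The mean log2 CPM of the cholesterol synthesis list was 5.22 in knockout 5 (others 5.06 to 5.07) and that of the cell cycle list 6.78 in knockout 7 (others 6.86 to 6.87). That of the B cell list was −0.68 in control 3, against −0.28 to −0.20 in the other controls.

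Of the 35 splits of the 8 samples into 4 and 4, only the labels' own, 1 split, gave as many as 674 changed genes. The highest other gave 10. This argues against chance for that count, but 1 of 35 is the smallest share possible, so chance is not excluded. By unadjusted p under 0.05 the labels gave 3468 genes and 3 other splits came near: 3408 and 3399 with knockout 7 exchanged for control 4 or control 2, and 2741 with control 1, control 3, knockout 5 and knockout 7 on one side. All 3 put knockout 7 with control 1 and control 3, which points to a structure of the samples besides the labels.

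Tgfbr1 was higher in the libraries labelled knockout. A single exchange of 1 control and 1 knockout label is argued against: over the 16 such exchanges the highest number of changed genes was 10, against 674. The unadjusted counts do not separate the exchanges of knockout 7 with control 4 or control 2 from the labels. Tgfbr1 itself was above every control in each of the 4 libraries labelled knockout, and 1 exchange would leave 3 of them. The choice of scaling is argued against too, with a lowest log2 change of 0.493 over 3 other scalings. These scalings moved the median log2 change of all genes little (−0.00134 to 0.0193), so an error shared by all of them was not tested. Other explanations stay open and untested: an exchange of all labels gives the same split, and gene-level counts do not separate reads of the removed part from the rest, nor a true rise of the gene.

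The uterine natural killer list was lower in knockout. Without control 1, its highest library, the median was −0.944, still below the bound set before it was computed. The difference of the list's score was −1.38 with all samples and −1.10 ± 0.413 (SE) without control 1. Control 2 to control 4 scored 2.57 to 2.92, above every knockout library (0.55 to 2.31), which argues against control 1 alone. That SE is too wide to clear the bound, so the share of control 1 in the fall cannot be told. With 1 surrogate variable the median was −0.872 and the score difference −0.912 ± 0.341 (SE), so structure of the samples apart from genotype cannot be told apart either. The change of the score minus that of red cell genes was −0.532 (exact permutation p = 0.0857), which leaves less blood in the knockout samples open. That test compares changes, not levels, so it does not show how much of these transcripts blood could carry. In control the mean score was 3.04 for the natural killer list and 1.32 for red cell genes. A lower number of these cells in knockout is also a hypothesis.

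Actg2, Acta2 and Tpm2 were higher in knockout. Myometrium left by the dissection stays open: 7 other smooth muscle genes, between 1 CPM and 10 times Actg2 in control, had a median of 0.249 ± 0.578 (SD over genes) against the 0.699 set as its bound, and they went both ways, from Tagln (0.96) and Myl9 (0.87) to Myocd (−0.70), none of them called. The mean of Myh11 was 1.18 CPM higher in knockout and that of Actg2 25.0 CPM higher. Knockout 8 alone is argued against: without it the log2 change of Acta2, the gene that kept least, was 1.18 ± 0.234 (SE) against 1.40, although the calls of Acta2 and Tpm2 were lost (adjusted p = 0.0577 and 0.121). A rise of these genes with genotype may remain as a hypothesis, found and tested on the same data.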

How the results depend on the processing

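Leaving out control 1 and knockout 7 together, and list tests with 1 surrogate variable, were chosen after seeing the data. No paired analysis was possible because the labels give no pair, litter or batch. Tgfbr1 kept its direction in every setting run, between 0.42 (without knockout 6) and 0.56 (without knockout 5) when 1 library was left out. All 154 other named genes kept their sign in every setting in which they were tested. Most were named for large changes or small p in this same fit, so their kept signs are little independent evidence.

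The 674 changed genes became 1747 with DESeq2 (900 higher, 847 lower, 623 at least 2-fold), 1415 with the edgeR likelihood ratio test (753, 662 and 601) and 1063 with limma-voom and sample quality weights (591 higher, 472 lower). They became 992 with 1 surrogate variable, which called 452 lower, and 99 at an adjusted p under 0.01. With both control 1 and knockout 7 left out there were 856. With 1 library left out the counts ran from 226 to 1235 (142 to 751 higher, 84 to 484 lower, 124 to 526 at least 2-fold), lowest without knockout 6 and highest without knockout 7. Fewer samples enter those fits, but the cause of the rise without knockout 7 was not tested. The other scalings and filters, and limma-voom with equal weights, gave 590 to 753. Camera called 11 lists at the preset correlation and 0 with an estimated one. Fry called 6, of which matrix proteases (adjusted p = 0.0247) was not among camera's 11. Some lists were called only under other settings, at the preset correlation, and an estimated correlation was run only with all samples and the main filter and scaling, where no list was called (adjusted p = 0.986 for cell cycle, 0.721 for T cells, 0.849 for immediate early genes, 0.445 for lymphatic endothelium and 0.373 for matrix proteases). They included cell cycle without control 1 and knockout 7 (median −0.125, adjusted p = 0.00368), T cells with the filter of 1 CPM (−0.77, 0.0125) and with total count scaling (−0.36, 0.0385), immediate early genes with total count scaling (−0.23, 0.04) and with no filter (−0.24, 0.0324), and lymphatic endothelium with no filter (−0.55, 0.0459). Matrix proteases were called with 1 surrogate variable (0.18, 0.00478) and without control 1 and knockout 7 (0.23, 0.0157). Without those libraries the erythroid median was −0.48 and the macrophage median −0.24. Totals of 45573335 counts or more still left genes such as Cd163 under 1 CPM, where small changes may be missed. Detection by expression level was not tested.

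The cause of the following sign changes was not tested, and none of these lists but macrophages was called with all samples. With 1 surrogate variable the medians were 0.0089 for angiogenic factors, 0.015 for coagulation, 0.049 for decidualisation, −0.029 for fibrillar collagens, 0.0089 for inflammatory cytokines, 0.118 for interferon response, 0.0038 for macrophages, 0.054 for p53 and 0.0069 for steroid synthesis. Without control 1 and knockout 7 they were 0.017 for angiogenic factors, 0.039 for endoderm, 0.010 for inflammatory cytokines, 0.098 for pericytes and 0.0059 for TGF-beta induced genes. Total count scaling gave 0.013 for angiogenic factors, 0.020 for blood endothelium, 0.022 for inflammatory cytokines and 0.015 for pericytes, and upper quartile scaling 0.0027, 0.0060, 0.0059 and 0.00014. The filter of 1 CPM gave 0.00097 for angiogenic factors, −0.55 for B cells, 0.0041 for blood endothelium and 0.183 for inflammatory cytokines. No filter gave 0.0040 for blood endothelium, 0.119 for endoderm and 0.223 for neutrophils. With 1 library left out the medians ran from −0.033 to 0.016 for angiogenic factors, −0.033 to 0.176 for B cells, −0.047 to 0.066 for blood endothelium, −0.116 to 0.029 for decidualisation, −0.196 to 0.201 for endoderm, −0.00048 to 0.106 for fibrillar collagens, −0.181 to 0.028 for inflammatory cytokines, −0.217 to 0.016 for interferon response, −0.303 to 0.251 for neutrophils, −0.072 to 0.013 for p53, −0.085 to 0.093 for pericytes, −0.135 to 0.0078 for TGF-beta induced genes and −0.098 to 0.793 for trophoblast.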

Other observations

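The observations here were chosen after the values were seen. Imprinted genes, which are expressed from 1 parental allele in at least some tissues, held several of the called increases. Whether they are expressed from 1 allele in these samples was not measured. Of 49 tested genes of a list of 56 written for this purpose, 8 rose and 0 fell. Zim1 rose by 1.17, Mirg by 1.05, Meg3 by 1.00, Rian by 0.95, Peg3 by 0.93, Dlk1 by 0.82, Ndn by 0.45 and Cd81 by 0.38 on the log2 scale (edgeR quasi-likelihood test, adjusted p from 0.00333 for Zim1 to 0.0445 for Ndn). Meg3, Rian, Mirg and Dlk1 lie in 1 imprinted cluster, and Zim1 and Peg3 in another. H19 had 0.57 with an adjusted p of 0.0952 and Slc22a3 −0.90 with 0.0688. The median over the list was 0.12, with 32 genes above 0 and 17 below. Camera gave an unadjusted p of 0.000464, and 0.00562 with an estimated correlation. As the list was drawn up because some of these genes were called, that p is too small by an unknown amount.

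A2m and Prl8a2 were higher in control 1, control 3 and knockout 7 than in the other libraries of the same group. A2m, a protease inhibitor, was at 27340, 10150, 23350 and 9553 CPM in control 1 to 4 and at 4357, 3059, 12670 and 3553 CPM in knockout 5 to 8. Prl8a2, a decidual prolactin family gene, was at 8371, 2819, 5795 and 2350 CPM in control 1 to 4 and at 3286, 2038, 5540 and 1436 CPM in knockout 5 to 8. The surrogate variable took its 3 highest values, 0.589, 0.331 and 0.349, in these libraries.

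Counts of 6 Y-linked genes summed to 2, 1, 2 and 7 in control 1 to 4 and to 25, 24, 13 and 4 in knockout 5 to 8, out of at least 45573335 counts each. Embryonic globins had 0 counts in every library. An embryo of day 6.5 need not express them, so this does not tell whether embryonic tissue was present. The mean log2 CPM of the trophoblast list was 1.97, 0.78, 1.11 and 0.83 in control 1 to 4. It was 2.35, 1.91, 0.94 and 0.58 in knockout 5 to 8. Prl3d1, a member of that list, had mean normalised counts of 630.5 in control and 988.25 in knockout in the authors' deposited table.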
